A study of Danio rerio with 8 samples.

How the data were processed

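RNA-seq was made from 8 samples of sorted zebrafish tumour cells, 4 from MYCN fish and 4 from myrAKT fish. Per the labels' protocols, tumours were broken up mechanically, EGFP-positive or mCherry-positive cells were sorted into Trizol-LS, and total RNA was extracted. The labels call the molecule polyA RNA, whereas their extraction protocol describes depletion of ribosomal RNA with a SMARTer low-input kit, NEBNext Ultra libraries and paired-end reads from an Illumina NextSeq; which of these selected the RNA is left open by the labels. The authors deposited 1 table of raw read counts per gene symbol, with 14781 rows and 1 column per library, and its values are whole numbers whose totals differ between libraries. The submitters' processing notes name the genome build GRCz10 and the tools FastQC 0.11.5, Trim Galore 0.4.4, TopHat2 2.1.1, SAMtools 1.5, HTSeq 0.6.1 and edgeR, without their order. The gene annotation, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. Counts of near-identical gene copies and of overlapping or antisense genes are therefore uncertain.

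Counts summed to between 36984845 and 55827123 per MYCN library and between 25948623 and 43083220 per myrAKT library. No row is a total or an unassigned class, and all columns matched a sample by name. Of the rows, 732 had no count in any library. Libraries were compared within groups by a chi-square of the counts of genes with a summed count of at least 10: over the 12 pairs the statistic per degree of freedom was between 21.2 and 286, so each library was counted as a separate sample. Gene symbols were used as deposited, and 12660 of them are current symbols and 14519 current symbols or synonyms in a RefSeq gene table of assembly GRCz12tu. No coordinates are given, since that table is of another assembly, and GC content and gene length were not analysed here.

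Differences between myrAKT and MYCN were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, which kept 12126 genes, TMM factors, and the quasi-likelihood F test (glmQLFit and glmQLFTest, robust, legacy off), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The TMM factors were between 0.747 and 1.04 in MYCN and between 1.10 and 1.22 in myrAKT. Log2 fold changes are myrAKT minus MYCN. Standard errors were derived from the fold change and its F statistic. CPM values are scaled with the TMM factors, and shares of all counts are percent of the unscaled library total. The submitters' notes name edgeR too, with settings that are not given in the sources used here.

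Before the data were examined, 27 gene lists were written: programs of the sympathoadrenal lineage, neuronal maturation, neuropeptides, the cell cycle, nucleolar and other MYC targets, ribosomal proteins, nuclear oxidative phosphorylation, glycolysis, sterol and fatty acid synthesis, the ATF4 response, the PI3K, AKT and mTOR pathway and FOXO targets; markers of glia, leukocytes, lymphocytes, erythroid cells, endothelium, stroma, interrenal steroid cells, kidney tubule, muscle, epithelium with pancreas and liver, and germ cells; and immediate-early genes, histones, MHC class I and mitochondrially encoded genes. Of 779 listed symbols 668 were found as written and 17 under an older symbol that the RefSeq table pairs with that gene alone. No row matched the mitochondrial list, and the histone list had fewer than 5 tested members. The other 25 were tested against all other genes with camera from limma 3.58.1 on voom log2 CPM, with a preset inter-gene correlation of 0.01 and adjustment over the 25 lists. Beside it stand the estimated correlation, fry, and the members past adjusted p 0.05 over all genes and adjusted over the list alone. A gene at 0 in a group was given the bound that 3 counts over that group allow in the list medians; this applied to 1 lymphocyte gene, pax5, and left the median of 5.35 as it was.

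The genes named in the text followed a rule also written beforehand: dbh, th, phox2a, phox2bb, hand2, mycn, myca, akt1, akt2, alk and mki67 in any case; per program list up to 3 members with the smallest adjusted p under 0.05 in the direction most passing members took and 1 in the other; per list of other cell types or handling the 2 members with the highest mean CPM; and the 6 largest changes in each direction among passing genes with mean log2 CPM of at least 3, separated groups and a gene symbol that is not a clone or locus name. The rule gave 92 genes.

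The tests were checked on counts simulated for the 12126 genes from the means and library sizes of this comparison. They recovered 49 of 100 genes changed 2-fold and 87 of 100 changed 4-fold, and called 3 unchanged genes. The median error of the log2 fold change was 0.16, and a list of 50 raised genes had camera adjusted p = 1.2e-61 against 0.827 for a list of 50 unchanged genes. Only the 2-fold and 4-fold genes were changed, as many up as down, and genes were drawn independently of each other. In the data 76.0% of the tested genes changed, so the simulation does not check scaling or false calls under so broad a change. It does not check camera's preset correlation either. Alternatives covered DESeq2 size factors, upper-quartile factors and library totals, other filters on low counts, DESeq2 1.42.0, limma-voom with and without sample weights, edgeR's robust and legacy settings, a replicate block, a stricter threshold, a test against a 2-fold change, and each library left out in turn. Chosen after the data were seen were a scaling of the libraries on the geometric mean of dbh and th counts, counts without the members of the lists of other cell types, counts without ribosomal RNA rows, and alternatives for the principal components. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.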

Results

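RNA was sequenced from cells sorted out of tumours of transgenic zebrafish. The MYCN group held 4 samples of EGFP-positive neuroblastoma cells from fish carrying a MYCN transgene, and the myrAKT group held 4 samples of mCherry-positive ganglioneuroma cells from fish carrying myristoylated AKT, a membrane-anchored form of this kinase. Neuroblastoma and ganglioneuroma are tumours of the sympathetic nervous system, the second being the more differentiated kind. Genotype, tumour type and the fluorescent protein used for sorting went together in every sample, so each difference below is one between 2 sorted tumour-cell populations that differ in all 3. Read counts summed to between 36984845 and 55827123 per MYCN library and between 25948623 and 43083220 per myrAKT library. The labels do not say how many fish stand behind each sample, so p-values measure the spread between these samples. The transgenes are not rows of the table analysed here, and the levels of the fish genes mycn, akt1 and akt2 do not check the genotypes.

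The comparison of myrAKT with MYCN asks how the transcriptomes of the sorted ganglioneuroma and neuroblastoma cells differ. Genes of blood, vessel and kidney cells and cell-cycle genes were higher in the myrAKT libraries, and genes of catecholamine cells, neurons, the nucleolus and the ribosome were lower. Of 12126 genes tested, 9220 changed (edgeR quasi-likelihood test, adjusted p under 0.05), which is 76.0% of them. In the myrAKT libraries 4565 genes were higher and 4655 lower; 3629 rose and 3061 fell by 2-fold or more. Every library of one group lay above every library of the other for 72.5% of all tested genes, where chance gives 2.86%. The first principal component of log2 CPM held 89.1% of the variance and separated the groups, and the second held 4.54% and set MYCN 4 apart from the other MYCN libraries. Correlations of log2 CPM across genes were between 0.963 and 0.991 within groups and between 0.672 and 0.740 between groups. With library totals in place of TMM factors 8855 genes passed, and 62.2% of them were higher in myrAKT against 49.5% with TMM. That scaling moved the median log2 fold change of all tested genes from -0.04 to 0.34. Of 25 gene lists, 14 passed camera with its preset correlation, 9 higher and 5 lower in myrAKT, and 20 passed fry. None passed camera with an estimated correlation, and 8 of the 35 splits of the libraries into 4 and 4 gave 14 lists or more. Of the lists that passed camera, only oxidative phosphorylation did not pass fry. The sterol, PI3K, FOXO, interrenal, epithelial, germ cell and MHC class I lists passed fry but not camera. Fry does not set a list against the other genes.

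**Figure D1:**
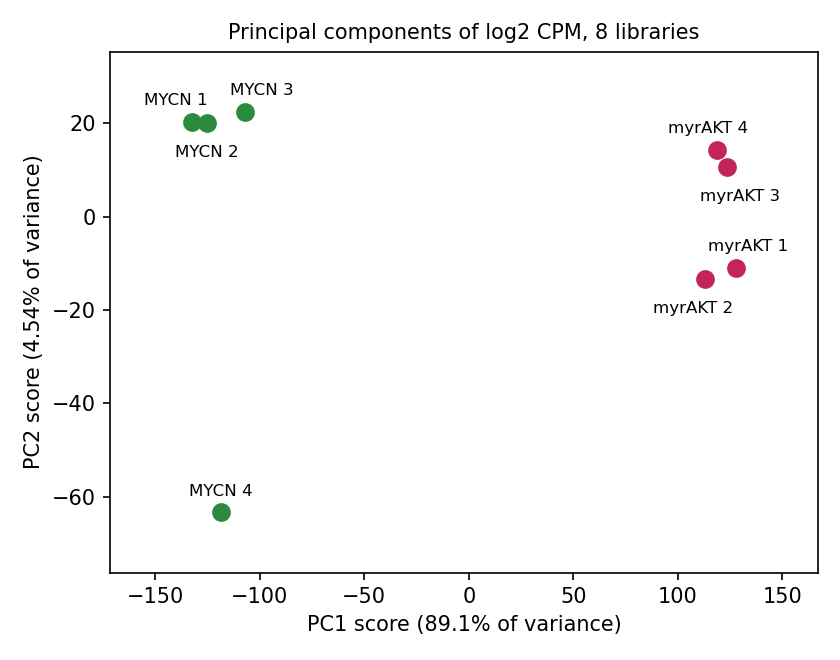
Scores of the 8 libraries on the first principal component (horizontal axis, 89.1% of the variance of log2 CPM) and the second (vertical axis, 4.54%), with MYCN libraries in green and myrAKT libraries in red. The groups separate along the first axis, and MYCN 4 has a second score of -63.42 where the other MYCN libraries lie between 20.04 and 22.54.

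Sympathoadrenal genes, which mark noradrenergic neurons and chromaffin cells, were mostly lower in the myrAKT libraries. Of 25 measured members 17 fell, 3 rose and 5 did not pass, with the same 17 and 3 adjusted over the list alone. Dbh, which makes noradrenaline from dopamine, averaged 1248 ± 377 CPM (SD, n = 4) in myrAKT and 3349 ± 304 CPM in MYCN, a log2 fold change of -1.42 ± 0.22 (SE; edgeR adjusted p = 2.4e-04). Th, the rate-limiting enzyme of catecholamine synthesis, fell by 1.33 on the log2 scale, from 2771 ± 545 to 1101 ± 374 CPM. Hand2 went from 1773 ± 369 to 277 ± 112 CPM (log2 fold change -2.68 ± 0.31, edgeR adjusted p = 3.4e-05), and phox2a from 572 ± 192 to 59.9 ± 19.1 CPM (log2 fold change -3.26 ± 0.34, edgeR adjusted p = 1.7e-05). Phox2bb fell by 2.35, tfap2b by 3.35 and mab21l1 by 2.58 on the log2 scale, and chgb, a protein of secretory granules, fell by 4.80. The strongest call in the other direction was eya1, at 8.17 ± 3.00 CPM in myrAKT and 0.182 ± 0.202 CPM in MYCN. The libraries were also scaled on the counts of dbh and th, a setting chosen after the data were seen that moved the median of all genes to 1.44. Under it 9 members fell, 6 rose and 10 did not pass. The list median went from -1.42 to -0.06, but both are the values of dbh itself, which this scaling sets near 0 by construction. Alk, also on the list of genes to be named, was not among the 12126 genes tested.

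Genes of neuronal maturation moved with them. Of 28 measured members 20 fell, 6 rose and 2 did not pass, again with 20 and 6 adjusted over the list alone. Scaling on dbh and th left 12 lower and 8 higher and took the median from -1.68 to -0.32. Elavl3, an RNA-binding protein of neurons, fell from 115 ± 27.1 to 2.56 ± 0.865 CPM (log2 fold change -5.51 ± 0.28, edgeR adjusted p = 2.1e-07). Cplx2, a complexin of synaptic vesicle release, fell by 3.63 and eno2, the neuronal enolase, by 3.10 on the log2 scale. The synuclein gene sncga went the other way, from 0.707 ± 0.471 to 14.9 ± 1.96 CPM. Against all other genes, camera gave adjusted p = 0.0024 for the sympathoadrenal list and 0.0039 for the neuronal list, both lower; neither held, with adjusted p = 0.559 and adjusted p = 0.557 with an estimated correlation. Of the 6 neuropeptide and processing genes tested, penkb and pcsk2 rose, cpe fell from 401 ± 73.3 to 173 ± 66.1 CPM, and 3 did not pass (camera adjusted p = 0.788; 2 higher and 1 lower adjusted over the list alone). On the dbh and th scaling 5 of them rose and none fell, where the median of all genes was 1.44. In the same libraries the markers of blood cells were many-fold higher in myrAKT, with lyz at 4282 ± 342 CPM against 44.0 ± 24.0 CPM.

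Ribosomal protein genes were lower in the myrAKT libraries almost without exception. They took 29.6 ± 4.01% (SD, n = 4) of all counts in MYCN and 13.3 ± 0.629% in myrAKT, and of 80 members 79 fell and 1, rps8b, rose (79 and 1 adjusted over the list alone). Rplp1 fell from 8191 ± 1452 to 1793 ± 164 CPM (log2 fold change -2.19 ± 0.17, edgeR adjusted p = 2.2e-06), rpl22l1 by 2.97 and rpl37 by 1.90 on the log2 scale. Of 32 nucleolar genes and other common targets of MYC proteins, 30 fell, none rose and 2 did not pass (30 adjusted over the list alone). Cad, which starts pyrimidine synthesis, fell from 1015 ± 110 to 307 ± 36.6 CPM (log2 fold change -1.72 ± 0.14, edgeR adjusted p = 3.1e-06). Srm, the spermidine synthase, fell by 1.98 and rrp12, a ribosome assembly factor, by 1.38 on the log2 scale. Camera gave adjusted p = 7.6e-14 for the ribosomal list (adjusted p = 0.557 with an estimated correlation) and 1.2e-07 for the nucleolar list (adjusted p = 0.557 with an estimated correlation). With libraries scaled on dbh and th the ribosomal median went from -1.56 to -0.03 and the nucleolar one from -1.52 to 0.02. Under it 77 of the 80 ribosomal and 26 of the 32 nucleolar genes did not pass, and 5 nucleolar genes were higher and 1 lower; rrp12 was at 0.14 on the log2 scale. Cpe, ndufaf5 and eif4ebp1, each lower with TMM, were then at 0.13, 0.13 and 0.055, without passing. The nucleolar median in MYCN 4 was a log2 CPM of 8.41, against 7.76 in the next MYCN library. Markers of blood cells rose in the myrAKT libraries, with medians of 4.11 for leukocyte and 6.15 for erythroid genes.

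Cell-cycle genes were higher in the myrAKT libraries. Of 33 members 30 rose, none fell and 3 did not pass (30 adjusted over the list alone), and their median log2 fold change was 1.97. Mki67, a marker of dividing cells, averaged 319 ± 104 CPM in myrAKT and 50.8 ± 3.09 CPM in MYCN (log2 fold change 2.65 ± 0.23, edgeR adjusted p = 4.0e-06). Top2a, the topoisomerase of mitotic chromosomes, rose from 27.4 ± 2.64 to 179 ± 42.4 CPM, kif11, a spindle motor, from 11.4 ± 0.961 to 83.4 ± 28.3 CPM, and foxm1, a mitotic transcription factor, from 1.67 ± 0.217 to 21.3 ± 7.62 CPM. Camera gave adjusted p = 2.5e-06 for this list (adjusted p = 0.557 with an estimated correlation). Over the 4 myrAKT libraries the median log2 CPM of the cell-cycle genes was 5.84, 6.13, 5.21 and 5.13, and that of the erythroid markers 7.98, 8.22, 7.23 and 7.14, for libraries 1 to 4.

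Among the lists of metabolism, glycolysis was higher, and nuclear-encoded oxidative phosphorylation was lower with TMM factors but took 1.14 ± 0.129% of all counts in MYCN and 1.104 ± 0.0700% in myrAKT (SD, n = 4). Of 22 glycolysis genes 14 rose, 3 fell and 5 did not pass (14 and 3 adjusted over the list alone; camera adjusted p = 0.020, adjusted p = 0.557 with an estimated correlation and 0.061 with libraries scaled on dbh and th). Pkma, a pyruvate kinase, rose from 401 ± 73.6 to 1359 ± 110 CPM (log2 fold change 1.76 ± 0.16, edgeR adjusted p = 5.2e-06), and gapdh from 3.18 ± 1.46 to 178 ± 74.2 CPM, whereas eno1b fell by 2.51 on the log2 scale. Of 81 oxidative phosphorylation genes 41 fell, 5 rose and 35 did not pass (41 and 5 adjusted over the list alone), and their median of -0.50 was -0.09 with library totals and -0.28 without MYCN 4, and turned to 1.00 with libraries scaled on dbh and th, where 63 rose and 1 fell and the median of all genes was 1.44. The 3 strongest calls among those that fell were ndufaf7, atp5s and ndufaf5, of which ndufaf7 and ndufaf5 are assembly factors of respiratory complex I, and ndufa4 rose from 1.74 ± 0.432 to 46.6 ± 5.46 CPM. Camera gave adjusted p = 0.0023 for this list, with adjusted p = 0.776 with an estimated correlation, and fry gave 0.092. Of 28 genes of sterol and fatty acid synthesis 15 fell and 7 rose (15 and 7 adjusted over the list alone; camera adjusted p = 0.194). Their median of -0.55 was -0.14 with library totals. It was 0.95 with libraries scaled on dbh and th, where 2 fell and 18 rose. With TMM factors elovl6, a fatty acid elongase, was at -2.84 and srebf1, a regulator of lipid synthesis, at 1.33 on the log2 scale. Of 25 genes of amino acid supply and the ATF4 response 11 fell and 9 rose (11 and 9 adjusted over the list alone), with slc3a2b, eif4ebp1 and atf5a lower and cebpb higher at 327 ± 43.8 against 19.9 ± 4.94 CPM. This list had a median of -0.05 while camera gave it a higher direction (adjusted p = 0.993), and the median was 0.03 with upper-quartile factors and 0.39 with library totals. It was between -0.21 without MYCN 1 and -0.005 without myrAKT 1 when single libraries were left out. The scaling on dbh and th gave 1.44, with 19 members higher and 1 lower. The markers of blood and kidney cells rose in the same libraries as the glycolysis genes and cebpb, with medians of 4.11 for leukocyte, 6.15 for erythroid and 5.81 for kidney tubule genes.

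Genes for parts of the PI3K, AKT and mTOR pathway went both ways with TMM factors: of 28 tested 13 rose, 9 fell and 6 did not pass (13 and 9 adjusted over the list alone; camera adjusted p = 0.611). Scaled on dbh and th, 22 rose and 1 fell, under a setting that called 8290 of all 12126 tested genes higher and 1041 lower. Akt1 rose from 19.1 ± 5.56 to 46.5 ± 4.53 CPM (log2 fold change 1.29 ± 0.20, edgeR adjusted p = 2.5e-04). Akt2 was at 156 ± 13.2 CPM in myrAKT and 204 ± 26.9 CPM in MYCN (log2 fold change -0.39 ± 0.13, edgeR adjusted p = 0.020), a call that ended with library totals (log2 fold change -0.03, adjusted p = 0.892) and without MYCN 2 (adjusted p = 0.052), myrAKT 3 (0.060) or myrAKT 4 (0.056). With libraries scaled on dbh and th akt2 was higher, at 1.11 on the log2 scale. Pik3cd, a PI3K subunit typical of leukocytes, rose from 53.4 ± 3.52 to 153 ± 4.70 CPM and rps6ka1, a ribosomal S6 kinase, from 31.6 ± 6.74 to 146 ± 17.5 CPM. Rheb, the small GTPase that activates mTORC1, fell from 51.1 ± 1.12 to 4.21 ± 1.44 CPM (log2 fold change -3.61 ± 0.23, edgeR adjusted p = 6.8e-07). Of 26 genes listed as targets of FOXO factors, which AKT holds out of the nucleus, 14 rose, 7 fell and 5 did not pass (14 and 7 adjusted over the list alone; camera adjusted p = 0.156). On the dbh and th scaling 20 rose and 2 fell. Klf2b and klf2a, transcription factors prominent in endothelium, averaged 176 ± 2.498 and 105 ± 4.88 CPM in myrAKT against 4.103 ± 0.924 and 7.23 ± 1.04 CPM in MYCN. Foxo1a rose from 0.890 ± 0.286 to 19.9 ± 1.95 CPM, and gabarapl2, a protein of autophagy, fell by 1.46 on the log2 scale. The endothelial markers rose in the same libraries, with fli1a at 101 ± 13.7 against 1.25 ± 0.246 CPM.

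**Figure D2:**
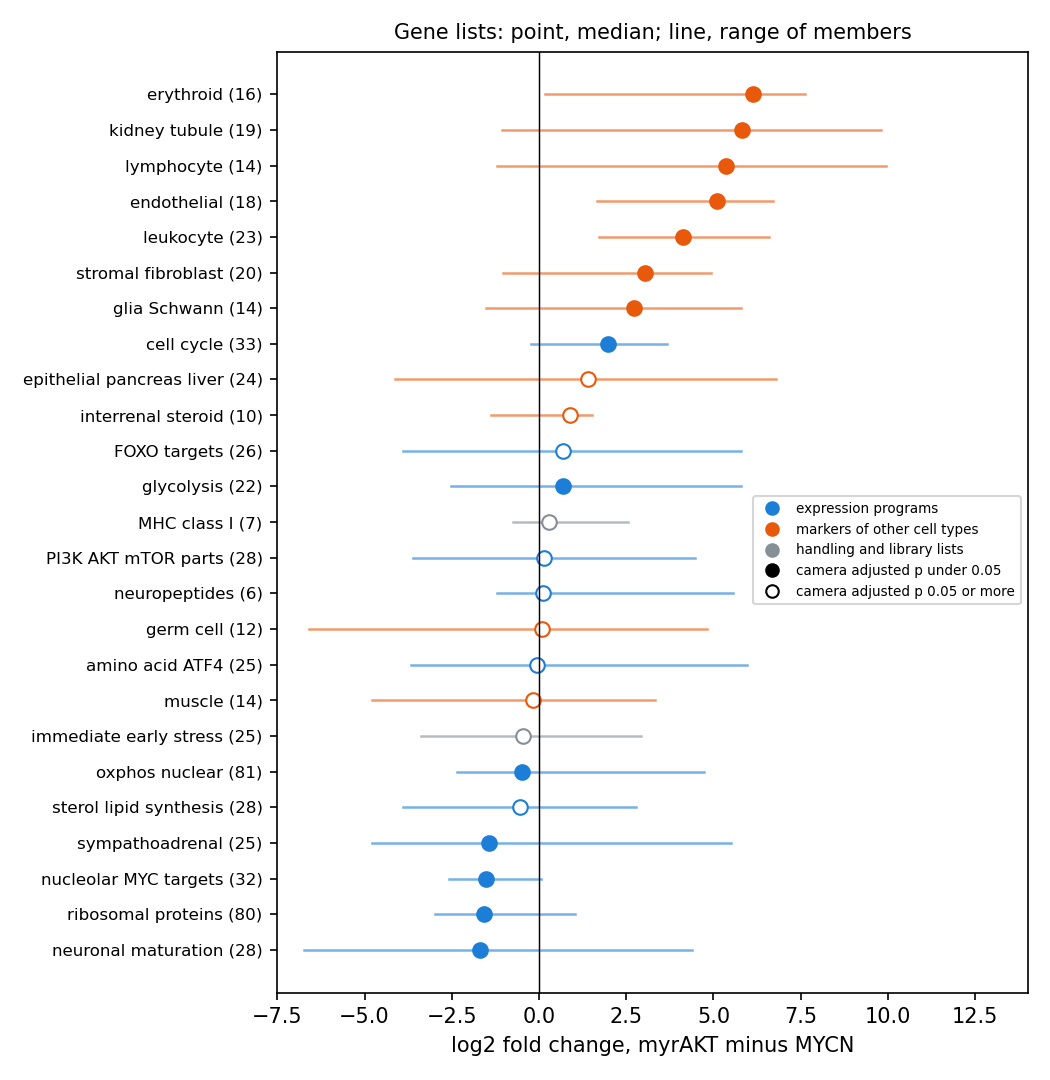
Median log2 fold change (myrAKT minus MYCN, horizontal axis) of each gene list as a point and the range of its members as a line, tested members in brackets, with a gene at 0 in a group placed at the bound that 3 counts over that group allow; filled points passed camera with its preset correlation, and none passed with an estimated one. Lists of blood, vessel and kidney markers lie to the right, up to a median of 6.15 for erythroid genes, and the neuronal, ribosomal, nucleolar and sympathoadrenal medians lie between -1.68 and -1.42, of which the nucleolar one turns to 0.02 with libraries scaled on dbh and th.

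Markers of other cell types were far higher in all 4 myrAKT libraries than in the MYCN libraries. Of 23 leukocyte genes 23 rose (median log2 fold change 4.11): lyz, the lysozyme of myeloid cells, averaged 4282 ± 342 CPM against 44.0 ± 24.0 CPM (log2 fold change 6.60 ± 0.40, edgeR adjusted p = 4.9e-07), and cd74a, of antigen-presenting cells, 6511 ± 1234 against 360 ± 207 CPM. Of 14 lymphocyte genes 13 rose and 1 fell (median 5.35), with ikzf1 at 147 ± 30.4 against 2.56 ± 0.626 CPM and ccr9a at 106 ± 8.70 against 4.23 ± 1.64 CPM. Of 16 erythroid genes 15 rose and 1 did not pass (median 6.15). The globin gene hbaa1 averaged 3449 ± 1435 against 71.3 ± 33.2 CPM, a value that may be shared with near-identical globin copies. Of 18 endothelial genes 18 rose (median 5.11), with stab1 at 158 ± 43.5 against 3.27 ± 1.59 CPM. Of 19 kidney tubule genes 17 rose and 1 fell (median 5.81): the sodium pump subunit atp1a1a.4 averaged 1206 ± 510 against 2.43 ± 1.40 CPM and the cadherin cdh17 912 ± 461 against 3.02 ± 1.95 CPM. Of 20 stromal genes 17 rose (median 3.05), with cxcl12a and fn1b as the most abundant, and of 14 glial genes 12 rose and 1 fell (median 2.72), with mbpb at 78.8 ± 8.11 against 27.7 ± 6.07 CPM. The counts adjusted over the list alone were the same for each of these lists.

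Camera gave adjusted p = 8.6e-09 for the leukocyte, 7.3e-05 for the lymphocyte, 6.5e-06 for the erythroid and 8.7e-07 for the endothelial list. Its adjusted p was 3.1e-04 for the kidney tubule, 1.1e-04 for the stromal and 0.0041 for the glial list. Each of these camera calls was lost with an estimated correlation, at adjusted p = 0.557. Fry gave these lists adjusted p between 5.0e-05 and 8.0e-04. Of 10 interrenal steroid genes 8 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.105, and 0.047 without myrAKT 1). Among them star, which brings cholesterol into mitochondria, was at 1028 ± 366 against 554 ± 180 CPM (edgeR adjusted p = 0.019), and the call ended without MYCN 2 (0.054), myrAKT 3 (0.055) or myrAKT 4 (0.058). Of 24 epithelial, pancreas and liver genes 13 rose and 5 fell (13 and 5 adjusted over the list alone; camera adjusted p = 0.084, and 0.036 without myrAKT 2), with krt8 at 1128 ± 47.9 against 107 ± 27.9 CPM and cpa5, a carboxypeptidase, at 656 ± 32.5 against 5.94 ± 1.67 CPM. With CPM of at least 1 in 4 libraries as the filter this list passed (camera adjusted p = 0.0053). For the interrenal and the epithelial list camera gave adjusted p = 0.612 with an estimated correlation under the reported settings. Of 14 muscle genes 5 fell and 3 rose (5 and 3 adjusted over the list alone; camera adjusted p = 0.703), and their median of -0.17 was 0.20 with library totals. This median was -0.89 without myrAKT 2, 0.24 without MYCN 3 and 0.17 without myrAKT 1. Under the dbh and th scaling 7 rose and 2 fell, where the median of all genes was 1.44. Of 12 germ cell genes 5 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.761).

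**Figure D3:**
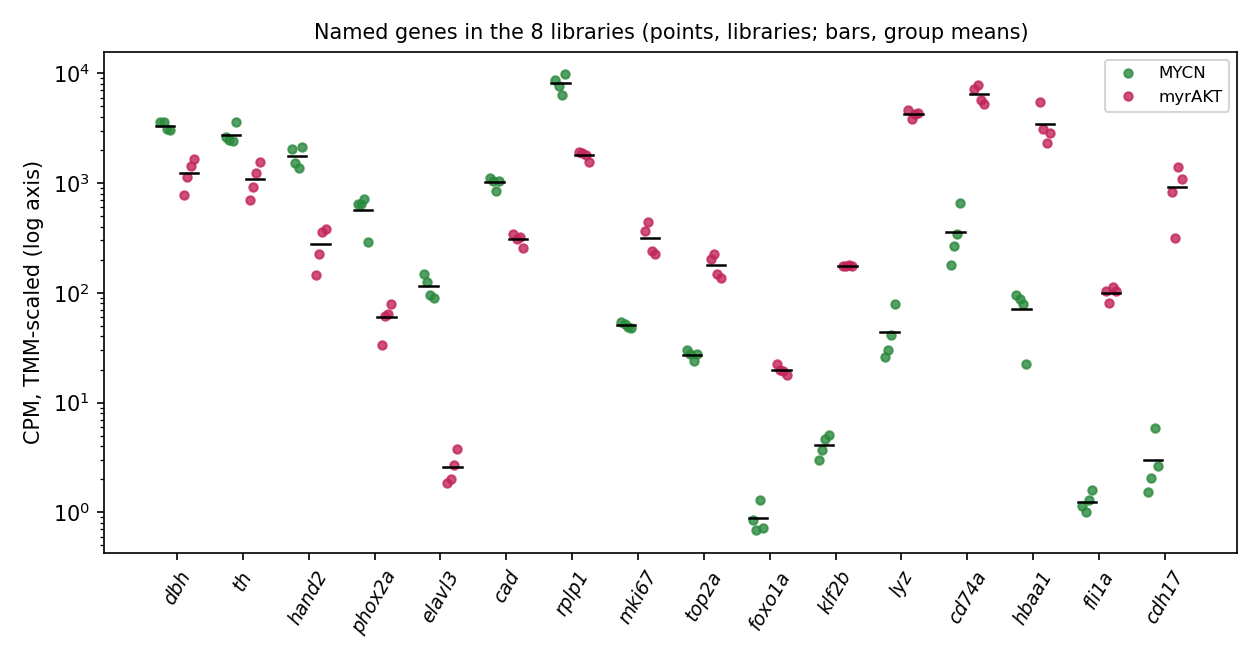
TMM-scaled CPM (vertical log axis) of 16 named genes in the 4 MYCN libraries (green points) and the 4 myrAKT libraries (red points), with group means as bars. Dbh, th, hand2, phox2a, elavl3, cad and rplp1 are lower in every myrAKT library than in any MYCN library, and mki67, top2a, foxo1a, klf2b and the blood, vessel and tubule genes at the right are higher.

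No list of handling or library make-up passed camera. Of 25 immediate-early and stress genes 9 fell and 7 rose (9 and 7 adjusted over the list alone; camera adjusted p = 0.761). Their median of -0.46 was -0.12 with library totals, -0.30 without MYCN 1 and -0.60 without MYCN 4. The scaling on dbh and th took it to 0.99, with 13 higher and 3 lower, where the median of all genes was 1.44. Jun was lower in myrAKT with TMM factors, at 36.7 ± 9.35 against 216 ± 52.9 CPM. Of 7 MHC class I genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.311). Their median of 0.28 was 0.75 with library totals and 0.82 without MYCN 4. Scaling on dbh and th made 6 of them higher and none lower. Mhc1uka rose by 0.87 on the log2 scale with TMM factors. Mhc1zba was at 53.8 ± 7.34 against 62.8 ± 14.8 CPM (edgeR adjusted p = 0.284, and 0.0497 without MYCN 4). With only 3 histone genes tested, hist2h2l fell and histh1l rose, and no list test was made. Counts on rows of ribosomal RNA were 1.87 ± 0.894% of the total in MYCN and 1.41 ± 0.383% in myrAKT (SD, n = 4).

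Among genes with a mean log2 CPM of at least 3, the 6 that rose most in myrAKT were mb, which encodes myoglobin, atp1a1a.4, cdh17, nt5c2l1, lrp2a and mmp13a. Mb went from 0.330 ± 0.0635 to 404 ± 182 CPM (log2 fold change 10.23 ± 0.52, edgeR adjusted p = 2.2e-07). Cdh17, atp1a1a.4 and lrp2a are also on the kidney tubule list and nt5c2l1 on the erythroid list, and the collagenase mmp13a rose from 6.66 ± 5.86 to 903 ± 119 CPM. The 6 that fell most were phyhipla, pmela, marcksb, mxb, mitfa and hhip. Phyhipla went from 127 ± 38.6 to 0.572 ± 0.168 CPM (log2 fold change -7.77 ± 0.33, edgeR adjusted p = 9.3e-08). Pmela, a pigment granule protein, fell from 223 ± 20.9 to 2.51 ± 0.298 CPM and mitfa, the regulator of melanophores, from 160 ± 75.4 to 2.27 ± 0.438 CPM. Hhip, which binds Hedgehog ligands, fell by 6.11 and marcksb by 6.26 on the log2 scale. The fish gene myca rose from 4.09 ± 0.218 to 40.6 ± 3.66 CPM (log2 fold change 3.31 ± 0.13, edgeR adjusted p = 7.5e-08), and mycn from 0.359 ± 0.180 to 1.47 ± 0.369 CPM (log2 fold change 2.03 ± 0.40, edgeR adjusted p = 0.0011).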

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

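Each group of 4 libraries was searched for a library that stands apart, by the gap to its nearest neighbour divided by the range of the group, over the named genes, the list medians, the library totals, the ribosomal RNA share and the second principal component. Of 242 groups 22 had a ratio above Dixon's critical value for 4 samples, which chance exceeds in about 5% of groups, and 13 of the 22 concerned MYCN 4. In MYCN 4 the second component score was -63.42, against 20.04 for the next library (ratio 0.971). MYCN 4 was lowest among the MYCN libraries for jun (0.981), atf5a (0.897), phox2a (0.874), hbaa1 (0.873), mycn (0.858), eno2 (0.858), ryr1b (0.853) and hhip (0.839), and for the median of the immediate-early list (0.983). It was highest for the medians of the oxidative phosphorylation (0.864), nucleolar (0.847) and glycolysis (0.839) lists. Phox2a in MYCN 4 was at a log2 CPM of 8.18, against 9.32 in the next library. No explanation was tested for this library; without it 9988 genes changed and 14 lists passed.

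Other MYCN libraries stood apart in 3 places: hmgcs1 was lowest in MYCN 1 (0.846), and mbpb (0.898) and the kidney tubule median (0.858) were highest in MYCN 3. Among the myrAKT libraries, myrAKT 4 was lowest for myca (0.968) and piwil2 (0.838) and highest for the stromal median (0.991). MyrAKT 2 was highest for srm (0.862) and the muscle median (0.895) and lowest for the median of the epithelial, pancreas and liver list (0.876).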

How the results depend on the processing

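The count of 9220 changed genes was between 8837 and 9988 with each library left out, and within 1.5 times under all other settings run except the test against a 2-fold change, which asks for more and called 5430. Up to 1 gene called in both was of opposite sign under these settings, apart from the scaling on dbh and th. The 14 lists were between 14 and 15 with each library left out, 0 with an estimated correlation (also at unadjusted p under 0.05; the cause was not tested), 20 by fry in its directional form and 25 by its mixed form, which asks another question. The first component held 89.1% of the variance, between 88.1 and 91.7 with each library left out and 86.2 without a filter; the cause was not tested. Over the named genes, 1553 of 1564 planned comparisons kept direction and call, 9 lost the call, 1 gained it and 1 changed sign without a call: mhc1zba, at 0.12 on the log2 scale with library totals. For the lists it was 363 of 399, with 15 lost and 21 gained, most of these by fry.

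The libraries scaled on dbh and th, an alternative chosen after the data were seen, called 8290 genes higher and 1041 lower, with 1026 of them opposite in sign to the reported call. Akt2 turned higher (1.11), as did mhc1zba (1.21), which had no call as reported. The calls of th (0.041), cpe (0.13), rrp12 (0.14), ndufaf5 (0.13), scdb (0.27), hmgcs1 (0.55), eif4ebp1 (0.055) and ryr1b (0.19) were lost, with values above 0 that did not pass, all log2 fold changes; by construction it sets dbh and th near 0.

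No pairing of the samples by replicate number was seen, though 4 pairs are too few to exclude it. Same-numbered libraries had correlations of deviations between -0.18 and 0.12, and 0 of 4 MYCN libraries correlated best with their own number. With a replicate block 8816 genes and 14 lists passed. Offsets for GC content, for length and for GC with the block were not run, for want of a genome. Depth limits the genes with few counts: over the 4 MYCN libraries penkb rested on 7 counts, eya1 on 28, mb on 53 and mycn on 56.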

Other observations

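Some gene families were singled out only after their values were seen, and these paragraphs describe them. Of 26 HOX genes tested 16 fell in the myrAKT libraries, 8 rose and 2 did not pass. The 8 that rose were near the floor, with means of at most 0.233 CPM in MYCN and 1.61 CPM in myrAKT. Summed, the HOX genes were at 1489.5 ± 157.6 CPM in MYCN and 149.8 ± 48.2 CPM in myrAKT. The abundant ones were of the hoxb cluster: hoxb8a went from 450 ± 259 to 39.7 ± 17.5 CPM (log2 fold change -3.51 ± 0.47, edgeR adjusted p = 8.2e-05), hoxb7a from 259 ± 68.5 to 21.0 ± 7.56 CPM and hoxb5a from 229 ± 71.2 to 23.2 ± 8.85 CPM. With libraries scaled on dbh and th 14 of the 26 still fell and 9 rose. All 6 fish genes of the MYC family tested were higher in myrAKT, also with that scaling, among them mycb at 40.4 ± 8.30 against 4.73 ± 1.68 CPM and mych at 56.8 ± 11.2 against 8.04 ± 1.94 CPM. Leukocyte, lymphocyte and erythroid markers rose in the same libraries, with medians of 4.11, 5.35 and 6.15, and that scaling raises RNA of other cells too. Of 10 melanophore genes 5 rose and 4 fell, kita rising from 0.669 ± 0.145 to 19.6 ± 1.90 CPM. Of 8 oncofetal RNA-binding and HMGA genes 4 fell, among them hmga1b from 87.0 ± 12.2 to 14.9 ± 3.53 CPM and igf2bp3 from 6.03 ± 2.31 to 0.637 ± 0.313 CPM. Of these 8 genes 3 rose, among them the most abundant, hmga1a, from 372 ± 28.6 to 765 ± 90.5 CPM. With libraries scaled on dbh and th 4 were higher and 3 lower.

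Of the tests below, those on library scaling and on splits of the samples were chosen before the results they measure were seen, and the others after. Of 35 splits of the 8 libraries only the real one gave as many as 9220 genes. The others gave 0 at the highest by edgeR and by limma-voom, and up to 1310 by edgeR at unadjusted p under 0.05. Each of them mixes MYCN and myrAKT libraries, so the group difference widens its within-group spread and lowers its count. The real split is 1 of 35, the least share this test can give. It argues against chance for the count of genes without excluding it. For the count of lists chance stays open: 8 of the 35 splits gave 14 lists or more, up to 16.

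Markers of blood, vessels and kidney were higher in the myrAKT libraries. Library scaling is argued against, since the leukocyte median was 4.15 or more under the other 3 scalings. A single program of the tumour cells that raises all of these markers is not settled. In 4 of the 6 pairs of myrAKT libraries the erythroid and kidney tubule medians moved in opposite directions by more than 0.5. All 4 set library 1 or 2 against 3 or 4, so they are 1 contrast over few libraries. It was seen before the test was chosen. Over libraries 1 to 4 the erythroid medians were 7.98, 8.22, 7.23 and 7.14 and the tubule ones 5.56, 4.42, 6.55 and 6.21. The 2 medians did not move together, which goes against such a program, but 1 contrast does not decide. RNA from several blood, vessel and kidney cell types in the sorted myrAKT samples may be the source and stays open: the medians of 5 of 5 such lists lay more than 1 above those of muscle and germ cells, but these medians are the pattern itself and add no support. Sorting on mCherry would remove such cells unless they were carried along or carried the marker, and which of these holds was not tested.

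Sympathoadrenal and neuronal genes were lower in the myrAKT libraries. Dilution of otherwise unchanged tumour-cell RNA is argued against as the whole cause, provided that dbh and th came from the tumour cells alone. That was not tested. With libraries scaled on dbh and th, 21 of the 53 members of both lists still fell, among them hand2, phox2a and elavl3. Under it 6 sympathoadrenal and 8 neuronal members rose. The sympathoadrenal median was then -0.06, which is the value of dbh itself and lies near 0 by construction. For dbh and th themselves dilution and lower expression cannot be told apart. With library totals the fold change of dbh would need 51.2% of other RNA. The fold change with TMM factors would give 62.7%, but TMM-scaled values are not shares of a library. No purity value measured apart from these genes was at hand. By library, dbh and th with library totals would need 69.3, 57.0, 42.9 and 26.2% of other RNA in myrAKT 1 to 4. Over these libraries the leukocyte median did not fall (8.95, 8.99, 9.17 and 9.21). The erythroid median was lower in libraries 3 and 4 (7.98, 8.22, 7.23 and 7.14). The kidney tubule median was higher there, so the markers did not go 1 way. A difference in state between ganglioneuroma and neuroblastoma cells stays open, as the design gives it and no test separated it.

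Ribosomal protein and nucleolar genes were lower and cell-cycle genes higher in the myrAKT libraries. The choice among the usual scalings is argued against: under the other 3 planned ones the ribosomal median was -1.15 or lower, the nucleolar one -1.13 or lower and the cell-cycle one 2.00 or higher. With libraries scaled on dbh and th the ribosomal and nucleolar medians were -0.03 and 0.02, where the median of all genes was 1.44, so that whether these genes fell in the tumour cells depends on the dilution below. Dividing cells of other types raising the cell-cycle genes remain a candidate explanation: all 4 myrAKT libraries had the same rank by cell-cycle and by erythroid median, an order over few libraries that was seen before the test was chosen and adds no support. Dilution of tumour-cell RNA with unchanged ribosomal protein transcripts cannot be told apart from lower expression over the 4 libraries as a set. The ribosomal percent left by the dilution was 9.07, 12.7, 16.9 and 21.8 in myrAKT 1 to 4. The observed percent was 13.8, 13.1, 13.7 and 12.4. In libraries 3 and 4 the percent left lay above the observed one, so the other RNA would hold less than no ribosomal protein RNA. In library 1 it lay below and left room for such RNA. In library 2 it lay only just below, at 12.7 against 13.1, and left little room. The difference in MYCN and AKT transgenes and tumour type stays open too, untested.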
